A study of Mus musculus with 14 samples.

How the data were processed

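Poly(A) RNA was measured by sequencing in mouse cardiomyocytes. Per the labels, newborn Rosa-Cas9GFP mice (postnatal day 1), which carry Cas9 and GFP at the Rosa locus, received an adeno-associated virus (AAV), either AAV-Ryr2gRNA, named for a guide RNA against Ryr2, or AAV-Cre, named for the Cre recombinase. At 4 weeks of age cardiomyocytes were isolated by Langendorff perfusion and purified by fluorescence-activated sorting. RNA was extracted with a PureLink micro-scale kit and turned into libraries with SMART-Seq v4, which amplifies full-length cDNA and does not mark the strand, and with Nextera XT. The labels name Cre for the control virus and the guide for the other virus, and whether the guide virus also carried Cre is not given in the sources used here, so effects of the guide and of the vector cannot be separated. The labels number 7 samples in each group (gRNA replicates 1 to 7 and control replicates 1 to 7). They do not say that these came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

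The deposited count table holds whole-number read counts per gene, not normalized, for 23337 genes in the 14 libraries. Per the submitters' processing notes, the tools were STAR, featureCounts, DESeq2 and DESeq with the genome build mm10; their versions, the annotation and the strand setting of the counting are not given in the sources used here. The file gives the position of each gene's exons, from which gene coordinates in mm10 and exonic lengths were taken. The authors' deposited table of their own comparison gives log2 fold changes, p-values and adjusted p-values for the same 23337 genes, and it was used only to describe that table beside the present fit. Per the file headers, the authors computed its mean signal per gene by dividing counts by size factors with DESeq2, and its score (the Wald statistic) by dividing the log2 fold change by its standard error. Its mean normalised counts equalled, within 0.1%, those that median-of-ratios scaling over all 14 libraries gives for 17089 genes. No row of the count table lacked a gene name, and 0 columns were left unmapped to a sample. SMART-Seq reads carry no molecular identifiers, so lower bounds for genes with a count of 0 cover counting error only. With unstranded reads, overlapping and antisense genes cannot be told apart, and counts of near-identical copies are uncertain.

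The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with the default filterByExpr filter, TMM scaling and no covariates. It was two-sided, with Benjamini-Hochberg (BH) adjustment over the 11170 genes that passed the filter, and a gene was called at an adjusted p under 0.05. Normalised counts relative to library size (CPM) were computed from the deposited counts with TMM-scaled library sizes, and are given as mean ± SD with n = 7 per group. Log2 fold changes are gRNA minus control. For genes with 0 counts in all controls the fold is a lower bound against a floor of 3 counts over the control group. Ryr2 was also compared by a two-sided exact permutation test over all 3432 assignments of the libraries.

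The design, the rule for named genes, 27 gene lists and most alternatives were fixed before the data were examined, but with knowledge of the study's subject, so the lists were not chosen blind. The rule named Ryr2; the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 3 and at least 6 gRNA libraries beyond the control median; the 10 remaining genes with the smallest adjusted p; up to 4 tested members of each list with the smallest p, and any needed to name a count of 5 or fewer; and, named in advance, further genes (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ddit3, Atf4, Hspa5, Xbp1 and Actn2). Gene models without a proper name were left out of the rankings. Some genes that the rule names are not reported here.

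The lists covered the ATF4 integrated stress response, endoplasmic reticulum (ER) chaperones, the p53, NRF2 and interferon responses, the proteasome, and autophagy. They also covered oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, glycolysis, calcium handling, the T-tubule, the adult sarcomere, fetal stress genes, ion channels, and cardiac transcription factors. The remaining lists covered cell cycle and immediate early genes, and markers of fibroblasts, endothelium, pericytes, macrophages, erythroid cells, atrial cardiomyocytes and a mixed Schwann, epicardial and adipocyte list. Mitochondrially encoded genes formed a list that was not analysed here. The erythroid list had a single tested gene, which left 25 lists for a set test. Some genes carry another symbol in the count table: Emr1 for Adgre1, Ifi27l1 for Ifi27, Pkm2 for Pkm, Ccdc109a for Mcu, H47 for Selenos and Beta-s for Hbb-bs.

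Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided and BH-adjusted over the 25 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in either direction without comparing them with other genes, were the alternatives. A two-sided exact permutation test of each list's mean log2 CPM per library was added after the data were seen. Like fry, this test does not compare a list with other genes.

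Alternatives set in advance were other scalings, filters and tests (DESeq2 1.42.0, limma-voom with sample weights, robust dispersion), a fold threshold, a block for the replicate number, the library total as covariate, and leaving out each library in turn. Terms for sex, for libraries 7 to 10 of the series' library index, and for macrophage markers were added after the data were seen, as were fits with and without those 4 libraries. On simulated counts with known changes for this comparison of 7 against 7 libraries (11077 genes), the main test called 52 of 100 genes changed by 0.5 on the log2 scale, 85 of 96 changed by 1 (88.5%), and 2 of 10881 unchanged genes. In a separate set of simulated counts, with each gene drawn independently, 2 of 2 lists shifted by 0.5 and 0 others of the 25 were called. Genes of the real lists are correlated (estimated at up to 0.92), so this does not give the rate of false list calls here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with tables read by pandas 2.3.3 and numpy 2.4.6.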

Results

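Gene expression was measured in sorted cardiomyocytes of 4-week-old mice that had received either a virus with a guide RNA against Ryr2 (gRNA group, n = 7) or a Cre virus (control group, n = 7) as newborns. Ryr2 encodes the ryanodine receptor of heart muscle, the channel that releases calcium from the sarcoplasmic reticulum at each beat. The total count per library ranged from 5689340 to 13165662. Its mean was 7748300 ± 2425550 in the controls and 7424540 ± 1742690 in the gRNA group (SD, n = 7 each). Between 13688 and 14719 genes had a count in each library. The biological coefficient of variation was 16.2%, and no pair of replicates was alike enough to be the same library deposited again (chi-square per degree of freedom between 4.82 and 28.5). Counts of Y-linked genes and of Xist marked 5 male and 2 female controls, and 4 male and 3 female gRNA samples.

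The first principal component of the libraries held 37.9% of the variance and separated the groups. The second held 24.2% and set apart 4 libraries, control replicates 4 and 5 and gRNA replicates 4 and 5, which follow each other in the series' library index (numbers 7 to 10). The labels name no batch for them, so values within these 4 libraries (2 of each group) and within the other 10 (5 of each group) are given beside the pooled values of most genes with the largest increases and of the called lists. The 20 most abundant genes took 22.9 ± 0.410% of the counts in controls and 20.7 ± 1.14% in gRNA libraries (SD, n = 7 each).

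Ryr2 itself was lower in every gRNA library than in any control library. The control libraries held 763, 751, 732, 649, 602, 620 and 605 CPM (replicates 1 to 7), and the gRNA libraries 371, 333, 301, 225, 324, 337 and 272 CPM. The means were 675 ± 71.4 and 309 ± 48.1 CPM (SD, n = 7 each), so that the gRNA group kept 45.8% of the control level. An exact two-sided permutation test over 3432 assignments gave p = 0.00058, the smallest it can give. The log2 fold change was -1.13 (SE 0.0977, adjusted p = 3.3e-07, edgeR quasi-likelihood test), and it was -1.11 among the other 10 libraries and -1.22 within library indices 7 to 10. Ryr2 lies on the minus strand of chromosome 13 at 11553103 to 12106945 (mm10), and its 105 annotated exons cover 16813 bp. The position of the guide in the gene is not given in the sources used here, and a transcript level does not measure the protein or the share of edited cells.

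The comparison asks how the transcriptome of these heart muscle cells differed when Ryr2 was targeted. The highest genes included enzymes and transporters of amino acids and endothelin 3. Most tested genes of the ATF4 and NRF2 stress responses were higher, and most of oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation were lower, although as lists all of these but NRF2 lost their call with an estimated correlation. Of 11170 genes tested, 1621 were higher and 1528 lower in the gRNA group (28.2% in all; edgeR quasi-likelihood test, BH-adjusted). A change of at least 2-fold was met by 277 of the higher genes and by 63 of the lower ones. In 1178 genes (10.5%) the values of the groups did not overlap, against 0.0583% by chance. The calls numbered 1379 higher and 1284 lower among the other 10 libraries, and 689 higher and 777 lower within library indices 7 to 10. With a term for those libraries the counts were 1891 and 1761.

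**Figure D1:**
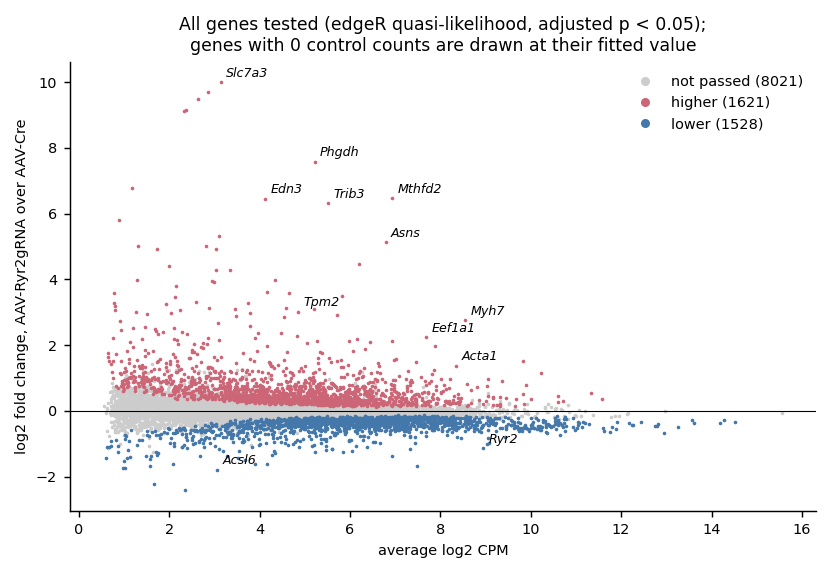
Log2 fold change (AAV-Ryr2gRNA over AAV-Cre, vertical axis) against average log2 CPM (horizontal axis) for the 11170 tested genes, with red for the 1621 higher, blue for the 1528 lower and grey for genes not passing. The largest folds are increases, and the abundant genes on the right are more often lower.

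Several of the 10 highest named genes encode enzymes or transporters of amino acids. Phgdh, the first enzyme of serine synthesis (chromosome 3, 98313171 to 98339969, minus strand), was nearly silent in controls at 0.362 ± 0.244 CPM and reached 73.0 ± 16.7 CPM (SD, n = 7 each, log2 7.57, SE 0.257, adjusted p = 4.0e-12). Mthfd2, a mitochondrial enzyme of folate metabolism (chromosome 6, 83305704 to 83317604, minus strand), rose from 2.69 ± 0.540 to 240 ± 80.0 CPM (log2 6.47, SE 0.231), and Asns, asparagine synthetase (chromosome 6, 7675171 to 7693182, minus strand), from 6.09 ± 1.86 to 214 ± 68.1 CPM (log2 5.13, SE 0.231). The amino acid transporter Slc7a3 (X chromosome) had 0 counts in the controls and 928 in the gRNA libraries, which makes it at least 295-fold higher against a floor of 3 counts over the control group. The transporters Slc6a9 (log2 5.32) and Slc7a5 (4.45), the proline enzyme Pycr1 (4.30), the pseudokinase Trib3 (6.31) and the stress-induced nuclear protein Nupr1 (4.92) were also among the 10 highest. Some of these folds were smaller within library indices 7 to 10 than among the other 10 libraries. The log2 fold change there was 4.89 against 6.60 for Trib3, 3.99 against 6.204 for Slc6a9, 3.24 against 4.84 for Pycr1, 4.24 against 5.19 for Nupr1, 5.90 against 6.65 for Mthfd2 and 4.12 against 4.57 for Slc7a5. For Trib3 it was 7.23 with the level of macrophage markers as a covariate, an alternative chosen after the data were seen.

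Edn3, which encodes the peptide endothelin 3 (chromosome 2, 174760773 to 174784042, plus strand), had the smallest adjusted p of all genes. It rose from 0.371 ± 0.213 to 33.8 ± 2.56 CPM (SD, n = 7 each, log2 6.46, SE 0.169, adjusted p = 1.1e-13). Further genes with small p were all higher. They included Aldh1l2 (log2 1.82) and Aldh18a1 (2.93), enzymes of folate and proline metabolism, Atp9a (1.55), Eef1a1 (2.25), and Mvp (1.45). Others were the cyclin Ccnd2 (1.13), Snd1 (0.98), the epoxide hydrolase Ephx1 (3.50) and the receptor kinase Grk5 (2.22). Eef1a1, a translation elongation factor, rose from 71.2 ± 11.99 to 339 ± 65.7 CPM, although it has many processed copies in the genome and its count is uncertain.

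Genes with the largest decreases fell by less. Acsl6, an acyl-CoA synthetase (chromosome 11, 54303824 to 54361539, plus strand), fell from 12.6 ± 2.43 to 3.63 ± 0.442 CPM (SD, n = 7 each, log2 -1.79, SE 0.137, adjusted p = 9.9e-08). The carboxylesterase Ces1d (chromosome 8, 93166072 to 93197804, minus strand) fell from 273 ± 42.9 to 85.6 ± 22.4 CPM (log2 -1.68). Tmod4 (-1.62) and Phkg1 (-1.62), genes of the thin filament and of glycogen breakdown in muscle, the histamine methyltransferase Hnmt (-1.49), Cmtm8 (-1.42), the mitochondrial carrier Ucp2 (-1.37), Plekhh1 (-1.37), the kinetochore gene Cenpf (-1.28) and the phospholipase Pla2g5 (-1.24) completed the 10 lowest. Among the other 10 libraries and within indices 7 to 10 the log2 fold changes were 7.34 and 8.64 for Phgdh, 6.22 and 7.23 for Edn3, 5.26 and 4.73 for Asns, and -1.84 and -1.71 for Acsl6. Each of these 10, and each of the 10 highest genes, lay beyond the control median in 7 of 7 gRNA libraries. The rule that named them already required at least 6, so this count is no separate support.

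**Figure D2:**
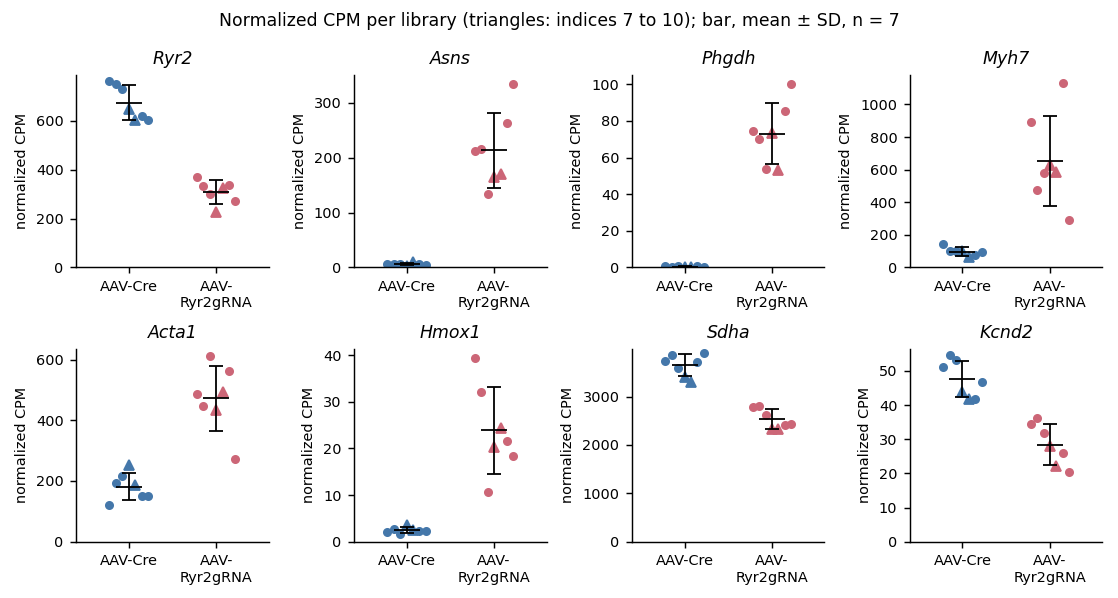
Normalised CPM of 8 genes in each library of the control (blue) and gRNA (red) groups, with triangles for library indices 7 to 10 and bars for the mean ± SD (n = 7). Every gRNA library lies outside the control range for each of these genes.

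Of the 25 gene lists with a set test, 15 were called with the preset correlation, 7 of them higher and 8 lower in the gRNA group. Each of these 15 calls was also made among the other 10 libraries and within library indices 7 to 10. The mean shift against other genes in these sets, in that order, was 0.85 and 0.77 for NRF2, 0.62 and 0.51 for p53, 0.38 and 0.42 for ER chaperones, and 0.64 and 0.42 for fetal stress genes. It was -0.48 and -0.55 for the tricarboxylic acid cycle, -0.46 and -0.43 for fatty acid oxidation, -0.41 and -0.35 for ion channels and -0.19 and -0.28 for the proteasome. For the adult sarcomere it was -0.19 and -0.35, for transcription factors -0.21 and -0.22, for glycolysis -0.15 and -0.19, for macrophage markers 0.96 and 1.38, and for the interferon response 0.24 and 0.47. With an estimated correlation a single call held, that of the NRF2 list. Among 100 splits of the same libraries, the real one included, 24 gave at least 15 called lists. The number of called lists thus did not set the real grouping apart. The other splits kept 4 to 6 of the 7 libraries of a group together, so they carry part of the group difference. Their counts are not those of data without one. An exact permutation test of each list's mean level per library, chosen after the data were seen and adjusted over the 25 lists, passed for 14 lists, 13 of them among the 15.

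The ATF4 integrated stress response, the transcriptional programme that follows phosphorylation of the translation factor eIF2 or a shortage of amino acids, rose as a group. Of its 38 tested members 33 were higher and 0 lower, and adjusted over the list alone 34 were higher and 1 lower, the exception being the lipoprotein receptor Vldlr. The median log2 fold change was 1.43 (camera adjusted p = 3.9e-27, adjusted p = 0.083 with an estimated correlation), also with the 3 genes at 0 in controls set at their bounds. The mean level was above all controls in 7 of 7 gRNA libraries (log2 difference 2.31, exact permutation adjusted p = 0.0024), and the shift against other genes was 2.39 among the other 10 libraries and 1.88 within indices 7 to 10. Beside Slc7a3, the cystine transporter Slc7a11 and the hormone Fgf21 had 0 counts in controls and were at least 238-fold and at least 175-fold higher (749 and 552 counts in the gRNA libraries). The 4 members besides Vldlr that did not pass over all genes were Ddit4, Cebpb, Ppp1r15a and Stc2. Atf4 itself rose by 0.61 (adjusted p = 0.010), but its log2 fold change was -0.12 within library indices 7 to 10 and 0.88 among the other 10. Ddit3, which encodes CHOP, rose by 0.59 (adjusted p = 0.038), a call that was lost on leaving out control replicate 1, 2, 4, 6 or 7 or gRNA replicate 2 (adjusted p = 0.050 to 0.083) and within indices 7 to 10 (log2 0.11).

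Chaperones and degradation factors of the ER rose more modestly and not as a whole. Of 31 tested members 23 were higher and 0 lower (24 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 1.2e-09, adjusted p = 0.24 with an estimated correlation, exact permutation adjusted p = 0.0024). The disulfide isomerase P4hb rose from 385 ± 4.73 to 656 ± 66.0 CPM (SD, n = 7 each, log2 0.77), Dnajb9 by 1.15, Ssr1 by 0.74 and Derl1 by 0.69. Xbp1, a transcription factor of the unfolded protein response, rose by 0.47 (adjusted p = 0.0021). The main ER chaperone Hspa5 did not pass, at 1583 ± 128 CPM in controls and 1667 ± 207 CPM in the gRNA group (log2 0.07, adjusted p = 0.53).

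Antioxidant genes of the NRF2 response rose, and this list kept its call with an estimated correlation (adjusted p = 0.027). Of 16 tested members 13 were higher and 0 lower, also adjusted over the list alone (13 and 0), with a median of 0.69 (camera adjusted p = 1.1e-08, exact permutation adjusted p = 0.0024). Hmox1, heme oxygenase 1, rose from 2.42 ± 0.627 to 23.9 ± 9.42 CPM (SD, n = 7 each, log2 3.29), sulfiredoxin Srxn1 by 2.20, the glutathione synthesis subunit Gclm by 1.20 and thioredoxin reductase Txnrd1 by 0.78. The members that did not pass were Prdx1, Txn1 and Mt1. The p53 and DNA damage list also rose. Of its 18 tested members 10 were higher and 1 lower (12 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 1.4e-04, adjusted p = 0.12 with an estimated correlation, exact permutation adjusted p = 0.0024). The cell cycle inhibitor Cdkn1a rose from 45.0 ± 21.5 to 199 ± 40.1 CPM (log2 2.13), the death receptor Eda2r by 1.98, Phlda3 by 1.21 and Aen by 0.66, and the lower member was Ccng1 (-0.26).

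Of 52 tested nuclear-encoded genes of oxidative phosphorylation 48 were lower and 0 higher (49 and 0 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 3.6e-21, adjusted p = 0.28 with an estimated correlation, exact permutation adjusted p = 0.0055). Sdha, a subunit of complex II, fell from 3647 ± 227 to 2531 ± 205 CPM (SD, n = 7 each, log2 -0.53). The complex I subunits Ndufa9 and Ndufs1 had log2 fold changes of -0.60 and -0.47. The 4 that did not pass were Ndufa2, Sdhc, Uqcrq and Cox6a2. Against other genes the list shifted by -0.46 among the other 10 libraries and by -0.68 within indices 7 to 10. Random lists matched on level and length had a median of -0.33, and abundant genes in general were lower. The median fold was -0.33 among the 122 genes above a mean log2 CPM of 10 and 0.14 among the 1235 genes at 2 or below. The 122 genes include members of this list, such as Sdha and Ndufs1, and other mitochondrial genes, such as Cs and Acaa2. The random lists left out only this list's own genes. Neither value is therefore a background known to be free of mitochondrial genes.

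In the tricarboxylic acid cycle list 17 of 18 tested genes were lower and 0 higher (18 and 0 adjusted over the list alone, median -0.44, camera adjusted p = 4.0e-13, adjusted p = 0.20 with an estimated correlation, exact permutation adjusted p = 0.0024). Citrate synthase, Cs, fell from 2612 ± 165 to 1866 ± 145 CPM (SD, n = 7 each, log2 -0.49). Sucla2, Pdhb and Suclg1 had log2 fold changes of -0.66, -0.58 and -0.50. Of 29 tested genes of fatty acid oxidation 22 were lower and 1 higher (24 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 3.3e-10, adjusted p = 0.29 with an estimated correlation, exact permutation adjusted p = 0.011). Acaa2 (-0.73), Hadhb (-0.63), Hadh (-0.61) and Eci2 (-0.49), enzymes of the oxidation of fatty acids in mitochondria, fell, and the higher member was the thioesterase Acot2 (0.65). In the list of glycolysis and glucose uptake 7 of 19 tested genes were lower and 2 higher (10 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.012, adjusted p = 0.52 with an estimated correlation, exact permutation adjusted p = 0.024). The list's mean level was 9.11 log2 CPM in controls. Among genes with a mean log2 CPM between 8 and 10, the median was -0.15 and 42.2% were lower. The list thus fell about as much as genes of its level in general. The muscle enzymes Eno3 (-0.62) and Pgam2 (-0.52) and the insulin-responsive glucose transporter Slc2a4 (-0.57) fell, while the transporter Slc2a1 (1.09) and the hexokinase Hk1 (0.32) rose. With the level of macrophage markers as a covariate, chosen after the data were seen, the shift of the glycolysis list went from -0.17 to -0.06 and its call was lost (camera adjusted p = 0.18).

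In the list of fetal and hypertrophic stress genes 15 of 23 tested members were higher and 2 lower, as also adjusted over the list alone (15 and 2, median 0.57, camera adjusted p = 1.4e-05, adjusted p = 0.12 with an estimated correlation, exact permutation adjusted p = 0.0055). Myh7, the slow myosin heavy chain of fetal ventricle (chromosome 14, 54970688 to 54994549, minus strand), rose from 96.7 ± 26.3 to 654 ± 277 CPM (SD, n = 7 each, log2 2.75, adjusted p = 6.7e-07). Its log2 fold change was 2.70 among the other 10 libraries and 2.85 within indices 7 to 10. The adult chain Myh6 stood at 49677 ± 3632 and 47618 ± 6257 CPM (log2 -0.06, adjusted p = 0.66). Skeletal actin Acta1 rose by 1.38, slow troponin I Tnni1 by 2.04 and Ankrd1 by 1.14. The natriuretic peptide gene Nppa (chromosome 4, 148000746 to 148002067, plus strand) rose from 468 ± 200 to 1349 ± 637 CPM (log2 1.53, adjusted p = 0.0023, with 1.45 and 1.63 in the same sets), and Nppb did not pass (log2 -0.26, adjusted p = 0.55). The lower members were Myh7b (-0.47) and Tnnt1 (-0.39). The call of Myh7b was lost on leaving out control replicate 1, 2, 3 or 4 or gRNA replicate 4 or 7 (adjusted p = 0.053 to 0.067). That of Tnnt1 was lost without control replicate 1, 2, 5 or 7 or any gRNA replicate but 3 (adjusted p = 0.056 to 0.11), and both missed the threshold within each set of libraries.

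Of the adult sarcomere genes 10 of 24 tested were lower and 1 higher (11 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 0.0012, adjusted p = 0.52 with an estimated correlation, exact permutation adjusted p = 0.024). The list's mean level was 11.2 log2 CPM in controls. Among genes above a mean log2 CPM of 10, the median was -0.33 and 65.6% were lower. Those genes include members of the list, such as Csrp3 and Myl3. The list thus did not fall more than genes of its level in general. Csrp3 (-0.47), the light chain Myl3 (-0.47) and Tmod1 (-0.34) fell, and the higher member was Pdlim5 (0.52), a Z-disc scaffold. Macrophage markers were called higher with the preset correlation. They did not pass with an estimated one (camera adjusted p = 0.55) or by mean level (exact permutation adjusted p = 0.082). With their level as a covariate, chosen after the data were seen, the sarcomere list's shift against other genes went from -0.23 to -0.09. The sarcomere call was then lost (camera adjusted p = 0.21). In the list of ion channels and gap junctions 12 of 24 tested genes were lower and 0 higher, also adjusted over the list alone (12 and 0, median -0.26, camera adjusted p = 1.4e-04, adjusted p = 0.12 with an estimated correlation, exact permutation adjusted p = 0.0024). The potassium channel gene Kcnd2 fell from 47.6 ± 5.40 to 28.4 ± 6.02 CPM (SD, n = 7 each, log2 -0.75), and Kcnv2 (-1.47) and Kcnj12 (-0.52) fell as well. The call of Kcnv2 was lost within library indices 7 to 10. Among cardiac transcription factors and metabolic regulators 7 of 25 tested were lower and 0 higher, as adjusted over the list alone (7 and 0, median -0.09, camera adjusted p = 0.012, adjusted p = 0.43 with an estimated correlation, exact permutation adjusted p = 0.048), among them Hopx (-0.82), Tbx5 (-0.49), Gata6 (-0.45) and Esrrg (-0.30). With the macrophage covariate the shift of this list went from -0.20 to -0.08 and its call was lost (camera adjusted p = 0.23).

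Calcium handling genes other than Ryr2 went both ways. Of 37 tested members 6 were higher and 9 lower (6 and 10 adjusted over the list alone), and the list was not called (median -0.13, camera adjusted p = 0.30). The calcium-binding protein Casq1, the skeletal calsequestrin, rose from 94.6 ± 22.7 to 218 ± 23.6 CPM (SD, n = 7 each, log2 1.21), the exchanger Slc8a1 by 0.84, and Rcan1, a target of calcineurin signalling, by 0.81. The calcium pump of the sarcoplasmic reticulum, Atp2a2, fell from 26253 ± 1942.5 to 20653 ± 1794 CPM (log2 -0.35, adjusted p = 0.0015). The T-tubule list, which shares 10 of its 20 members with other lists, was not called either (1 higher and 5 lower, also adjusted over the list alone, median -0.10, camera adjusted p = 0.13). Its higher member was Slc8a1, and its lower members were Jph1 (-0.43), Mtss1 (-0.41), Cav3 (-0.31), Mtm1 (-0.25) and Asph (-0.17). The call of Mtss1 was lost without control replicate 1, 2 or 5 or gRNA replicate 2, 6 or 7 (adjusted p = 0.061 to 0.078), and that of Asph without control replicate 1, 2, 3, 6 or 7 or gRNA replicate 2, 4, 5 or 7 (adjusted p = 0.050 to 0.10).

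Proteasome subunits were slightly lower, with 15 of 31 tested lower and 1 higher (20 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 1.7e-05, adjusted p = 0.52 with an estimated correlation, exact permutation adjusted p = 0.024). Psmb2 (-0.34), Psma2 (-0.31), Psmb7 (-0.29) and Psmc3 (-0.23) had the smallest p. The higher member, Psmd11 (0.18), lost its call without control replicate 3, 4 or 6 (adjusted p = 0.052 to 0.059). Of 21 tested autophagy and lysosome genes 6 were higher and 0 lower, also adjusted over the list alone. The autophagy receptor Sqstm1 rose from 457 ± 24.8 to 862 ± 117 CPM (SD, n = 7 each, log2 0.91), Ctsl by 0.61, Atg7 by 0.47 and Ctsd by 0.30. That list was not called (median 0.10, camera adjusted p = 0.077), although its mean level passed (exact permutation adjusted p = 0.039), and the camera call was made without control replicate 7 or gRNA replicate 5 (adjusted p = 0.037 each). The immediate early list was not called (median 0.06, camera adjusted p = 0.53). Its higher members of 22 were Myc, from 2.997 ± 1.33 to 23.5 ± 11.9 CPM (log2 2.98), and Fosb (1.36), and adjusted over the list alone Myc remained. The call of Fosb was lost within indices 7 to 10 and on leaving out control replicate 1, 3, 6 or 7 or gRNA replicate 1, 3, 4, 5 or 7 (adjusted p = 0.057 to 0.086). Junb (0.57) did not pass over all libraries but did without gRNA replicate 6 (adjusted p = 0.039), Hspa1b (1.17) did not pass, and the heat shock gene has a near-identical copy. Of 17 tested cell cycle genes Ccnd2 and Mcm4 (0.48) were higher and Cenpf lower, also adjusted over the list alone. The call of Mcm4 was lost within indices 7 to 10 and with the macrophage covariate. Mcm6 (0.62) did not pass over all libraries, but passed without control replicate 5 (adjusted p = 0.035). The cell cycle list was not called either (median 0.06, camera adjusted p = 0.63).

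**Figure D3:**
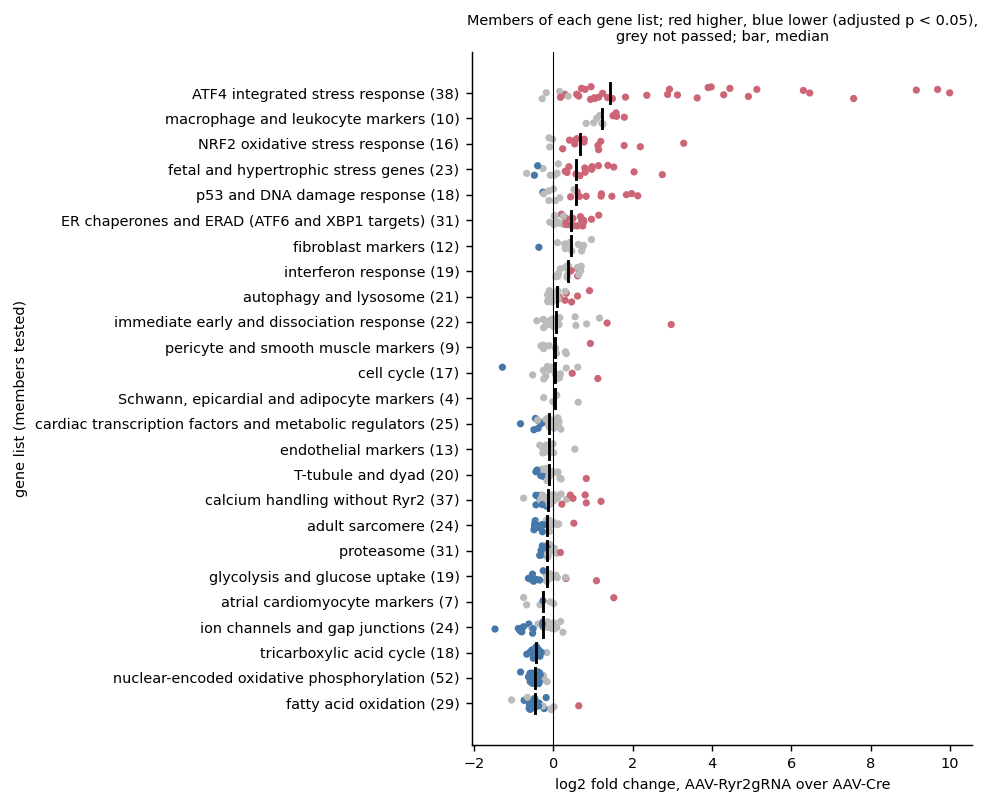
Log2 fold change (AAV-Ryr2gRNA over AAV-Cre) of every tested member of the 25 lists, with red for higher, blue for lower and grey for not passing, and a black bar at each list's median. The ATF4 list has its median at 1.43, and the 3 lists of mitochondrial oxidation lie between -0.47 and -0.44.

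Markers of other cell types were measured because the sort can leave some of their RNA behind. Macrophage and leukocyte markers were higher, with 4 of 10 tested members higher and 0 lower (6 and 0 adjusted over the list alone, median 1.24, camera adjusted p = 0.012, adjusted p = 0.55 with an estimated correlation). The lysozyme gene Lyz2 rose from 18.0 ± 10.3 to 62.2 ± 54.7 CPM (SD, n = 7 each, log2 1.79), the invariant chain Cd74 from 6.84 ± 2.71 to 20.4 ± 12.01 CPM (log2 1.59), Emr1 by 1.597 and C1qb by 1.51. The calls of Emr1 and C1qb were lost without control replicate 1, 2, 3, 6 or 7 or gRNA replicate 4 or 5 (adjusted p = 0.061 to 0.12 and 0.070 to 0.13). The list's mean level did not pass over all 14 libraries after adjustment (log2 difference 1.09, exact permutation p = 0.049, adjusted p = 0.082). It was 0.93 higher in the gRNA group among the other 10 libraries (n = 5 each, exact permutation p = 0.0079) and 1.501 higher within indices 7 to 10, where n = 2 each allows no exact permutation p below 0.33. With the macrophage covariate the autophagy list was called higher (camera adjusted p = 0.0069). The cell cycle (camera adjusted p = 0.047), fibroblast (9.9e-05), endothelial (1.8e-09) and pericyte (0.012) lists were called lower. This covariate varied with the group and with the library indices. Its mean was 4.75 (gRNA) and 3.25 (control) within indices 7 to 10, against 2.67 and 1.74 among the other 10. Fibroblast and endothelial markers were also higher within those indices, so these changes cannot be ascribed to macrophage RNA. By fry, which does not compare a list with other genes, the macrophage list did not pass (adjusted p = 0.073).

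Interferon response genes had 3 higher members of 19, Ifit2 (log2 0.62), Irf7 (0.61) and Ifi27l1 (0.45), of which Ifi27l1 and Ifit2 remained (2 of 19) adjusted over the list alone. Ifit3 (0.65) did not pass over all libraries, but passed without control replicate 5 or gRNA replicate 7 (adjusted p = 0.015 and 0.024). The list was called by camera (median 0.36, adjusted p = 0.021, adjusted p = 0.65 with an estimated correlation) but not by its mean level (exact permutation adjusted p = 0.18) or by fry (adjusted p = 0.15), and with the macrophage covariate its shift was -0.10. The camera call was lost without control replicate 2 or 7 or gRNA replicate 4 or 5 (adjusted p = 0.055 to 0.11), and that of Irf7 without control replicate 1, 2, 4, 6 or 7 or gRNA replicate 3, 4, 5 or 6 (adjusted p = 0.055 to 0.090). Within indices 7 to 10 the calls of Ifi27l1 (adjusted p = 0.12), Ifit2 (0.052) and Irf7 (0.10) were lost, as they were with the macrophage covariate (0.087, 0.11 and 0.37), and that of Irf7 also among the other 10 libraries (0.082) and with a term for sex (0.054).

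Endothelial markers, with 0 of 13 passing, were not called (median -0.09, camera adjusted p = 0.37). Their shift against other genes was -0.40 among the other 10 libraries (camera adjusted p = 0.0081), 0.14 within indices 7 to 10, and -0.43 without gRNA replicate 4 (camera adjusted p = 0.035). Of 12 tested fibroblast markers Fbln1 (log2 -0.36) was lower, also adjusted over the list alone, while Col1a1 (0.96), Col1a2 (0.77) and Postn (0.73) did not pass (median 0.44, camera adjusted p = 0.80). The list's shift was 0.016 among the other 10 libraries and 0.70 within indices 7 to 10. Cspg4 (0.94) was the 1 higher gene of 9 tested pericyte and smooth muscle markers, also adjusted over the list alone (camera adjusted p = 0.98). Of 7 tested atrial markers Nppa was higher and Kcnj3 (-0.26) lower, also adjusted over the list alone. Their median was -0.26 and their camera direction down, while the mean level lay 0.12 higher (camera adjusted p = 0.87, exact permutation adjusted p = 0.88). The call of Kcnj3 was lost without control replicate 2, 3, 4, 5 or 6 or gRNA replicate 3, 4 or 5 (adjusted p = 0.056 to 0.10). It was also lost among the other 10 libraries, with no filter, with the replicate block and with the macrophage covariate. None of the 4 tested Schwann, epicardial and adipocyte markers passed (camera adjusted p = 0.98), and the single tested erythroid gene, the globin Beta-s, did not pass either (log2 1.28, adjusted p = 0.18).

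Around Ryr2 the neighbouring genes did not move together. Of 22 other genes tested within 3 Mb, 6 were higher and 4 (Gm10336, Mtr, Mrpl32 and Psma2) lower. The next gene measured on the same strand, Gm10336 (13, 12182717 to 12186488), had a log2 fold change of -1.35 (SE 0.134, adjusted p = 1.6e-06), and Mtr, methionine synthase (13, 12186540 to 12258113 in the count table), had -0.71 (SE 0.109, adjusted p = 1.2e-04). Both were named after their values were seen, and Gm10336 lies wholly within the last exon of Mtr in GENCODE M21, so their counts are not separate evidence. Actn2, which follows Mtr at 12269427 to 12340732, stood at 4649 ± 307 and 4491 ± 399 CPM (SD, n = 7 each, log2 -0.05, adjusted p = 0.63). Beyond it, Heatr1 (0.44) and Ero1lb (0.74), chosen in the same way, were higher.

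**Figure D4:**
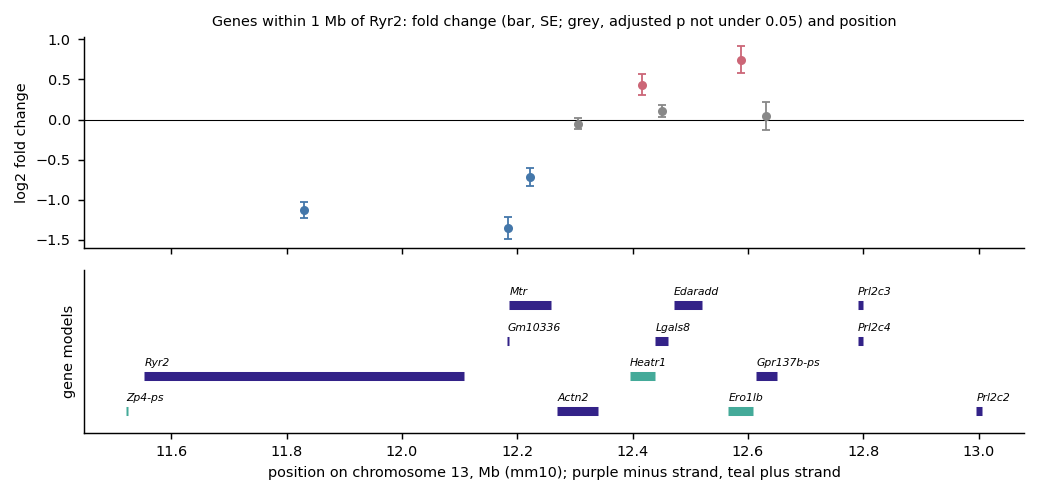
Log2 fold change (AAV-Ryr2gRNA over AAV-Cre, bars SE) of tested genes within 1 Mb of Ryr2 by position on chromosome 13 (mm10, in Mb), above the gene models on the minus (purple) and plus (teal) strands. Ryr2, Gm10336 and Mtr are lower, Heatr1 and Ero1lb higher, and grey points did not pass.

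The authors' deposited table gives 1674 genes as higher and 1621 as lower at an adjusted p under 0.05, among 13515 genes with an adjusted p. At 0.01 the authors' deposited table holds 1156 higher and 1155 lower. Its log2 fold change for Ryr2 is -1.14, and that for Phgdh is 7.63 in the authors' deposited table. Of the 3149 genes called here, 3003 (95.4%) are also called in the authors' deposited table, all 3003 with the same sign, while 146 are called here alone and 105 of the 11170 tested genes in that table alone. Across these genes, which are not independent replicates and come from the same counts, Pearson's r between both sets of log2 fold changes was 0.9996.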

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

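The tests of oxidative metabolism, macrophage markers and the genes beside Ryr2 were chosen only after the results were seen, while the 3 counts over other splits of the libraries were planned.

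Among 100 splits of the 14 libraries into groups of 7, the real one included, 1 gave as many higher genes as the real split (1621). Likewise 1 gave as many lower genes (1528). In both cases it was the real split, and 1 in 100 is the smallest share this test can give. Both counts are thus unlikely by chance, which 100 splits cannot exclude. Other splits have no direction of their own, so the larger of their counts was taken for both, and its highest value was 480. At least 15 lists, the real number, were called in 24 of the 100 splits, the real one among them (highest other 20), so chance was not excluded for the number of called lists. The other splits carry part of the group difference, because each kept 4 to 6 of the 7 libraries of a group together. Yet a split with only 4 together called 18 lists and 0 genes. Camera with a preset correlation therefore carries less weight here than the values of single genes and the exact permutation tests of the lists. Those exact tests do not compare a list with other genes. A list of abundant genes can thus pass them without a shift of its own, since abundant genes in general were lower.

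Genes of oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation were lower in the gRNA group. Dilution by RNA of other cells would lower sarcomere genes alike, but the oxidative level changed by a further -0.257 (log2, exact permutation p = 0.0012, n = 7 each; oxidative -0.43, sarcomere -0.18), which argues against dilution as the whole cause. Random lists matched on level and length had a median of -0.325 (95% of them between -0.38 and -0.19) against -0.46 for the list. The list's median lay below that range. However, the random lists drew each gene independently, while the list's own genes were correlated (estimated at 0.81). The range is therefore too narrow to decide on a general fall of abundant or short genes as the whole cause. The random lists left out only the list's own genes and could draw other mitochondrial genes, so the share of a general fall cannot be told. A response to the loss of Ryr2 or to the vector may account for part of the fall, as a hypothesis that the groups alone do not separate.

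Macrophage markers, a list fixed in advance whose members are in no other list, were called higher in the gRNA group with the preset correlation although sorting would remove such cells, but not with an estimated correlation (adjusted p = 0.55), by fry (0.073) or by the mean level over all 14 libraries (exact permutation adjusted p = 0.082). A lower share of cardiomyocytes would raise endothelial markers alike, but macrophage minus endothelial markers differed by 1.28 (log2, exact permutation p = 0.00058, n = 7 each). Only endothelial markers were compared in this way. Fibroblast markers differed by 0.25 over all libraries (exact permutation p = 0.56), 0.77 within indices 7 to 10 (n = 2 each) and 0.047 among the other 10. Endothelial markers differed by 0.24 within those indices and by -0.35 among the other 10. A lower share of cardiomyocytes thus stays possible within indices 7 to 10. These 4 libraries did not account for the higher macrophage markers, since the macrophage level differed by 0.932 among the other 10 (exact permutation p = 0.0079, n = 5 each). All 10 of 10 tested members had a positive fold, but these genes were correlated (estimated at 0.88) and are not separate observations. In the fibroblast list, which was not called, 11 of 12 were positive too. In the gRNA group Lyz2 stood at 62.2 ± 54.7 CPM, C1qb at 21.4 ± 20.2 CPM and Cd74 at 20.4 ± 12.01 CPM (SD, n = 7). More such cells in the heart, carry-over in the sort and expression by cardiomyocytes all stay possible, and the first may reflect a response of the tissue.

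Mtr and Gm10336, next to Ryr2 on the same strand, were lower. Of Gm10336, 100% lies within exons of Mtr in GENCODE M21, and the log2 levels of both had r = 0.951 across the 14 libraries, so a single transcript is a candidate source of both. A fall of all genes around Ryr2 is argued against by the 5 other tested genes within 1 Mb, whose mean log2 fold change was 0.257 (percentile 92.0 among 1923 random genes). An effect of cutting at Ryr2 on Mtr and a regulated change of Mtr stay open, and neither was tested.

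A library far from the other 6 of its group was found in 22 of 325 groups tested, against 16.25 by chance (about 1 in 20). The gap to the nearest library, as a share of the group's range, is given for each. Total counts stood apart in control replicate 1 (0.822) and gRNA replicate 7 (0.671), both the deepest of their group. In 9 groups the library was gRNA replicate 7, highest in Ddit3 (0.762), Myc (0.647), Ctsl (0.622), Dnajb9 (0.621), P4hb (0.608), Rcan1 (0.595), Eef1a1 (0.582) and Atf4 (0.5682) beside its total. For Ddit3 it held 48.6 CPM against 25.01 in the next library, and for Atf4 162 against 107. Control replicate 1 was highest in Tnnt1 (0.703) and Atp9a (0.573) and lowest in Fbln1 (0.627). Control replicate 7 was highest in Ces1d (0.742) and Kcnv2 (0.653). Other controls stood highest in Hspa1b (replicate 2, 0.621), Fabp4 (replicate 5, 0.620), Nppb (replicate 3, 0.617) and Slc2a1 (replicate 6, 0.594). gRNA replicate 3 was lowest in Eda2r (0.697) and in the mean level of the NRF2 list (0.581), and gRNA replicate 2 highest in Beta-s (0.731). By edgeR, 0 genes had an effect that differed between sexes at an adjusted p under 0.05 (177 at an unadjusted p under 0.05), and 0 between indices 7 to 10 and the others (339). Both unadjusted counts are below the 1 in 20 of 11170 genes that chance would give. Some sets held only 2 libraries of a group, so equal effects are not shown.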

How the results depend on the processing

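Fits with a term for sex, with a term for library indices 7 to 10, without or with only those 4 libraries, and with a macrophage marker covariate were chosen after seeing the data. The other alternatives were planned. Where a value turned, the cause was not tested. By construction, an added fold threshold can only lower a count of called genes. The macrophage covariate likewise removes the macrophage list's own shift, and it varies with the group and with library indices 7 to 10.

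Higher and lower genes numbered 689 and 777 with indices 7 to 10 only (2 libraries of each group), and 277 and 63 with an absolute log2 fold change of at least 1. With an estimated correlation 1 list was called. In all other settings the counts stayed within 1.5 times the main ones, with 1433 to 1664 higher and 1284 to 1527 lower genes on leaving out 1 library. With the replicate number as a block they were 1922 and 1848, and Ryr2 was at -1.14, although libraries of the same number correlated at 0.0614 to 0.533 and the numbers did not pair the samples. Ryr2 stayed between -1.18 and -1.05 on leaving out 1 library. Of 112 called among 136 named genes, 111 never turned, and 85 were called in every setting. Of 360 values of the 15 called lists, 335 kept direction and call, 23 were no longer called and 2 turned. At this depth, spread and number of libraries, 52 of 100 simulated genes changed by 0.5 were called, and depth alone was not varied.

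Atf4 was the called gene that turned, at -0.119 with indices 7 to 10 only. The other genes that turned there did not pass over all libraries: Kdr (0.0647), Myh11 (-0.545) and Wt1 (0.380). List shifts turned there for pericyte (0.235), cell cycle (-0.150), atrial (-0.386) and endothelial (0.141) markers.

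Without indices 7 to 10, Upk3b (0.249), Notch3 (-0.0576) and the shifts of the cell cycle (-0.0157) and Schwann (-0.0197) lists turned. Upk3b also turned with DESeq2 (0.00586), limma-voom (0.0956), the replicate block (0.0701) and the term for indices 7 to 10 (0.0255). The pericyte shift turned with a stricter filter (0.0520), and the Schwann shift with the library total as covariate (-0.0137).

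With the macrophage covariate the genes that turned were Col1a1 (-0.504), Postn (-0.410), Col1a2 (-0.449), Vwf (-0.311), Notch3 (-0.482), Myh11 (-0.101), Msln (-0.192), Myh6 (0.0479) and Actn2 (0.0470), none of them called. List shifts turned for macrophage (-0.0144) and interferon (-0.0977) lists, both called before, and for cell cycle (-0.424), immediate early (-0.130), fibroblast (-0.657), atrial (-0.397) and Schwann (-0.548) lists.

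On leaving out 1 library, uncalled values ranged on both sides of 0 for Upk3b (-0.186 to 0.217) and Myh6 (-0.103 to 0.00316), and for the shifts of pericyte (-0.145 to 0.101), Schwann (-0.147 to 0.223), cell cycle (-0.0586 to 0.149), atrial (-0.223 to 0.337) and fibroblast (-0.0299 to 0.373) lists.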

Other observations

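The gene groups and gene pairs below, and the test of the pairs, were chosen only after the results were seen, while the 3 correlations were planned. Some of the groups hold genes already named above for their values, such as Ephx1, Mvp and Edn3. The camera p-values of the groups, adjusted over these groups alone, therefore describe them and do not test them.

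Of 71 tested cytosolic ribosomal proteins 48 were higher and 0 lower (median log2 fold change 0.46, camera adjusted p = 2.2e-12, 0.24 with an estimated correlation), although near-identical copies make their counts uncertain. Of 76 mitochondrial ribosomal proteins 43 were lower and 0 higher (median -0.27, camera adjusted p = 6.2e-14, 0.20 with an estimated correlation). Genes of N-glycosylation and translocation into the ER had 13 higher and 1 lower (Tusc3, -0.27) of 23, with Sec61a1 at 1.17 and Rpn2 at 0.75 (camera adjusted p = 2.0e-06, 0.19 with an estimated correlation). Transport from ER to Golgi had 14 higher and 1 lower (Sar1b, -0.29) of 24 (camera adjusted p = 9.9e-06, 0.16 with an estimated correlation). Of 16 glutathione and detoxification genes 10 were higher, among them Ephx1 (3.50), Akr1b8 (3.14) and Mvp (1.45), and 3 lower, namely Gstt1 (-0.93), Gstk1 (-0.65) and Akr1b10 (-0.51) (camera adjusted p = 2.3e-05, 0.16 with an estimated correlation).

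Genes of secreted ligands went both ways, with 9 of 27 higher and 5 lower (camera adjusted p = 0.089, 0.16 with an estimated correlation). Beside Edn3, the higher ones were Bmp2 (3.96), Gdf15 (3.91), Tgfb2 (3.10), Tgfb3 (2.07), Ctgf (0.97), Hbegf (0.41), Fgf21 and Ostn. Ostn, which encodes osteocrin, had 0 counts in controls and 657 in gRNA libraries (at least 209-fold higher over a floor of 3 counts in the control group). Apln (-1.21), Bmp7 (-0.90), Angpt1 (-0.67), Vegfa (-0.49) and Vegfb (-0.48) were lower.

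Adult heart forms of muscle genes and their partner forms were compared in 24 pairs, chosen with the values in view and including genes named above, so their tally describes these pairs and does not test a general turn. The ratio of partner to adult form rose in 17 pairs at an exact permutation adjusted p under 0.05 and fell in 1, Phka2 to Phka1, and 6 did not pass. Shifts in log2 ratio were 3.52 for Tpm2 over Tpm1, 2.48 for Tnni1 over Tnni3, 2.29 for Rpl3 over Rpl3l, 2.01 for Eef1a1 over Eef1a2, 1.64 for Slc2a1 over Slc2a4 and 1.39 for Casq1 over Casq2. The adult form was lower in 15 pairs, the partner higher in 10, and both in 6.

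Whether the spread between the 7 gRNA libraries relates the remaining Ryr2 to other genes was examined in 3 relations. Spearman's rho was 0.286 between Ryr2 and the ATF4 list (exact permutation p = 0.56), -0.0714 between Ryr2 and the oxidative phosphorylation list (p = 0.91) and 0.214 between both lists (p = 0.66), each with an adjusted p of 0.91. Pearson's r was 0.159 (exact permutation p = 0.73), 0.0467 (p = 0.93) and 0.371 (p = 0.41), each with an adjusted p of 0.93. Without the 2 libraries farthest from the median r was 0.736, -0.361 and 0.956 (n = 5). Library indices 7 to 10 hold 2 gRNA libraries, too few for a value of their own. With 7 libraries no relation was found, and the direction of any cannot be told apart from chance.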
